A study of Drosophila melanogaster with 3 samples.

How the data were processed

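Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in whole Drosophila melanogaster embryos of mixed sex, collected 0 to 10 hours after laying. The flies carried a stably expressed transgene of CG16815, an uncharacterised protein, with a green fluorescent protein (GFP) fused to its C terminus, and the tagged protein was precipitated with an antibody against GFP. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800. The labels give 1 group of 3 biological replicates and no second condition, so the comparisons the design implies are those between replicates, between regions that passed the authors' threshold and those that did not, and between sites and the genome around them.

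The deposited files are lists of called regions in the narrowPeak format, each made by the authors for 2 genome builds, dm6 and dm3. Per the README text deposited with the lists, each replicate has a relaxed list that holds peaks and background. A further relaxed list derives from the 3 alignments pooled. Each relaxed list also derives from 1 further file whose nature that text does not give. The final list derives from the 3 replicate lists and the pooled list, at an irreproducible discovery rate (IDR) threshold. Peaks were thus called per replicate and on the pool, and no control library was analysed here. The aligner, the peak caller, their versions and the threshold itself are not given in the sources used here. The signal value of each region is the authors' own, as their peak caller wrote it. Its normalisation is not stated, so signal was used to rank regions within a list, and values of separate lists were compared by rank only. The lists also hold the -log10 of a q-value for each region, deposited by the authors. It was used only to describe the lists, because 2680 of the 3922 regions of the final dm6 list share its highest value. The score and p-value columns hold a constant in every list and were not used. Read counts were not analysed here, so the depth of each library is unknown, and binomial and Poisson intervals cover counting error over sites only.

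The final dm6 list held exactly the 3922 regions with the highest signal of the pooled list, so the IDR step set how many regions were kept and not which. These are called passing sites, and the 14842 regions of the pooled list with no summit within 150 bp of a passing summit are called regions that did not pass. N is 3922 throughout, and the N best-ranked summits of each replicate stand for that replicate wherever a mean and SD over 3 replicates is given.

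Summits within 150 bp of each other were counted as shared. Chance was taken from 1000 seeded shuffles of the summits within each chromosome arm and, added after the data were examined, from 100 draws of N random regions of each replicate's list. The rank correlation of signal was Spearman's rho across passing sites found in both replicates. Sites are not independent replicates, so no p-value was attached. Summits were placed, in this order of priority, in promoters (within 500 bp of an annotated transcription start site, TSS), 5' UTRs, coding exons, 3' UTRs, other exons, introns or intergenic sequence of the Ensembl release 115 annotation (BDGP 6.54), which has dm6 coordinates. Transposable element genes were left out. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 7 classes. The X was compared with 2L, 2R, 3L and 3R by an exact binomial test on counts given the arm lengths.

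A gene was called bound when a passing summit lay within 500 bp of any of its TSSs. The gene lists, 30 in number, were fixed before the data were examined. Their members were tested against all other protein-coding genes of the chromosome arms (all genes for the 2 classes of small RNA genes) by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Of the names given, 6 matched no gene uniquely and were left out. Further names fell away because they gave a gene already in the list or one off the chromosome arms tested. Some lists thus tested fewer genes than names given, such as 23 genes from 27 names for architectural and insulator proteins. Odds ratios have 0.5 added to each cell. The 26 motifs, also fixed before the data were examined, were searched on both strands within 50 bp of each passing summit and in a window of the same 101 bp centred 450 bp to a side drawn at random. The windows were compared by the exact McNemar test with Benjamini-Hochberg adjustment over the motifs, and each motif read backwards, not complemented, served as a control for base composition. The 8192 7-mers were tested in the same way.

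Genes and sites were named by a rule fixed before the data were examined. It took the 25 passing sites with the highest signal among those with a summit within 150 bp in all 3 replicate lists, up to 4 bound members of each gene list with the highest signal, and CG16815. A site takes the name of the protein-coding gene with the nearest TSS within 500 bp, otherwise of the gene it lies in, otherwise its position. Coordinates are dm6 and 1-based. The dm3 lists were compared with the dm6 lists by count, width and concordance only, and no coordinate was converted.

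GC content around CG16815 was compared with that of regions of replicate 3 within 250 ranks by a permutation test with 100000 resamples, chosen after the data were examined. Genomic stretches with a GC at or under the median of passing summits and flanks at or above the median of theirs were compared between promoters and elsewhere within strata 5 percentage points wide (Mantel-Haenszel), and differences in rho were given intervals by 1000 bootstrap resamples of sites. On simulated data, planted shares of 30, 60 and 90% shared summits among 3922 were recovered as 30.7, 60.4 and 90.1%. Of 2 gene lists planted among 13945 genes, 100% were recovered over 100 rounds, and 0.346% of 2600 tests of unchanged lists were called. The planted lists were cytoplasmic ribosomal proteins (85 genes) and odorant and gustatory receptors (179 genes), each with a share bound far from that of other genes. Recovery of such large lists with strong effects does not measure the power for small lists or weaker effects. Left against right flanks of the passing sites gave 0 called 7-mers and 0 called motifs, and a 7-mer planted in 2 or 5% of the 3922 windows ranked 1 by p each time. Shuffled labels of the 18764 pooled regions gave p under 0.05 for the promoter share in 3.50% of 200 rounds. Alternatives fixed before the data were examined were summit distances of 50 and 300 bp or any overlap of intervals, the best-ranked 1961 or 7844 summits, the dm3 lists, the 1961 passing sites with the highest signal, promoter distances of 250 and 1000 bp, TSSs of protein-coding genes only, densities per gene instead of per Mb, genes with a pooled summit as background, the nearest gene only for each summit, windows of 100 bp either side, regions that did not pass as background for motifs, also within promoters alone, 6-mers, and each replicate left out in turn. Alternatives chosen after the data were examined were location compared within strata of summit GC 5 percentage points wide (Mantel-Haenszel), the sites shared by replicates 1 and 2, each motif against its reversed form, and the random draws named above. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.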

Results

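The data are lists of regions called from ChIP-seq of GFP-tagged CG16815 in Drosophila melanogaster embryos aged 0 to 10 hours. The replicate and pooled lists hold background as well as peaks. The 3 biological replicates form 1 group. Replicate 1 held 30000 called regions, replicate 2 held 21989 and replicate 3 held 27358, and the pooled list held 18764. Of these, 4062 regions of replicate 1, 6640 of replicate 2, 4396 of replicate 3 and 6047 of the pooled list had a q under 0.05. Replicate 1 had exactly 30000 regions on both builds, and whether a limit on the number called set this is not given in the sources used here, so shares and densities over its whole list depend on where it ended. The authors' IDR threshold kept 3922 sites, with a median width of 416 bp and a median signal of 218.4. Sequencing depth is unknown, since the lists give no read counts, and the intervals given here cover counting error only.

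The locus of CG16815 itself was examined first, because the tagged transgene adds a copy of this gene. CG16815 (FBgn0032491) lies on chromosome arm 2L at 13229832 to 13230549 (dm6). Replicate 3 had 21 called regions within 20 kb of it, 5 of them among its N best-ranked, whereas replicate 1 had 3 and replicate 2 had 4. At each list's density over the chromosome arms, 8.32 regions were expected in replicate 3, 9.12 in replicate 1 and 6.69 in replicate 2. The stretch from 13220803 to 13235186, which holds the gene, runs between a summit of replicate 2 and a summit of replicate 1 with none of either inside, and held 13 of replicate 3, of which 11 had no summit of the other replicates within 150 bp. A single passing site lay in the window, at 13222249 to 13222664, 7375 bp from the gene, with a signal of 256.4 and rank 1576. It had a summit within 150 bp in replicate 3 alone, and was 1 of 10 such sites in the whole list.

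**Figure D1:**
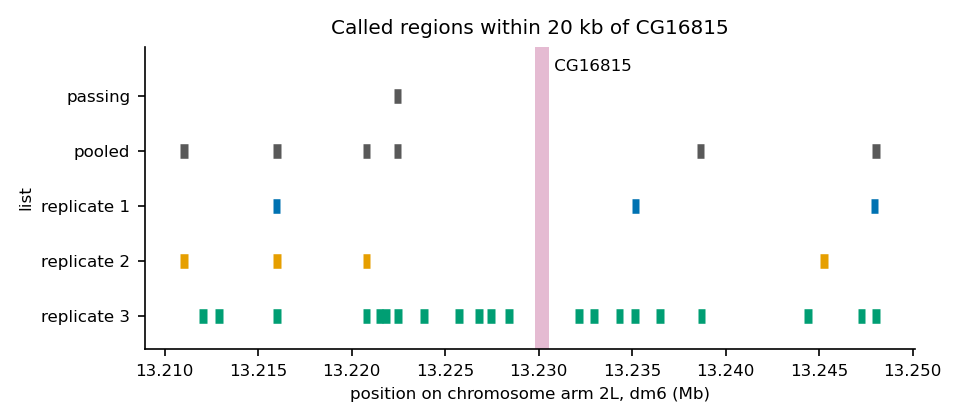
Called regions within 20 kb of CG16815 on chromosome arm 2L (x axis, position in Mb, dm6) in each list (y axis), with the gene as a vertical band. Replicate 3 has 21 regions, replicate 1 has 3 and replicate 2 has 4.

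Comparison of the replicates asked how far they recovered the same sites. Replicates 1 and 2 shared 78.4% of their 3922 best-ranked summits, replicates 1 and 3 shared 60.7% and replicates 2 and 3 shared 67.1%, a mean of 68.7% ± 8.94 (SD, n = 3 pairs). Shuffled summits shared 0.885% on average and at most 1.56%, and regions drawn at random from the same lists, a level added after the data were examined, shared 4.92% on average and at most 6.68%. The order of the sites by signal differed more between replicate 3 and the others. Spearman's rho across passing sites was 0.833 for replicates 1 and 2 over 3660 sites, 0.518 for replicates 1 and 3 over 3430 sites and 0.536 for replicates 2 and 3 over 3638 sites. Sites are not independent replicates, so no p was computed. Among the 250 best-ranked summits, replicates 1 and 2 shared 85.0%, and each pair with replicate 3 shared 59.6%.

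Passing sites were found in 93.8% of cases in replicate 1 (95% exact binomial interval 93.0 to 94.5), 99.3% in replicate 2 (98.9 to 99.5) and 93.4% in replicate 3 (92.5 to 94.1). These sites were called on the pool of the same 3 replicates, and each whole list holds background, so part of this recovery was built in. All 3 replicates held 3416 sites (87.1%), a pair of them held 480, and 26 sites were found in 1 replicate. Within the N best-ranked summits of each replicate the share found was 81.8% ± 8.75 (SD, n = 3), and 2230 sites (56.9%) were in the N best of all 3.

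**Figure D2:**
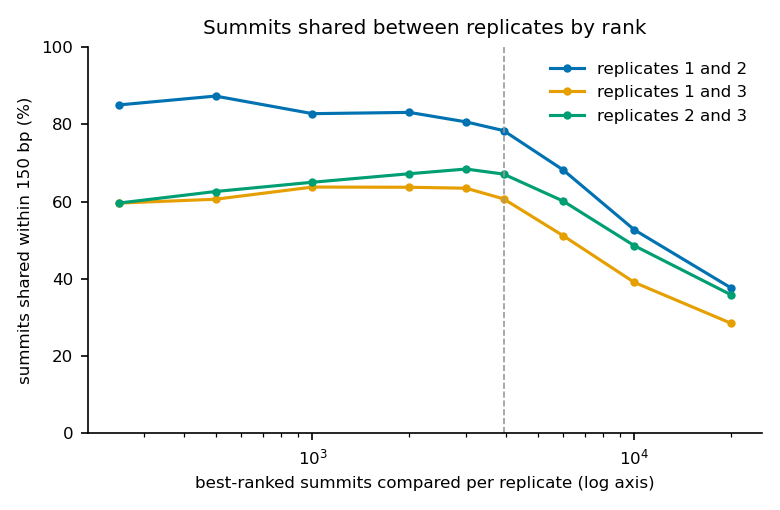
Share of summits within 150 bp of a summit of the other replicate (y axis, %) against the number of best-ranked summits compared (x axis, log scale) for the 3 pairs of replicates, with a dashed line at N, 3922. Replicates 1 and 2 share more at every number compared.

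The 25 strongest sites found in all 3 replicates lay at genes of several kinds. The highest signal, 3571.3, was at 19590402 to 19590835 on 3L, 96 bp upstream of the TSS of CG14100, and it ranked 2, 1 and 4 in replicates 1, 2 and 3. The next, with a signal of 3562.3, lay at 480862 to 481310 on 2L in an intron of ush, which encodes a cofactor of GATA transcription factors. Promoters of px (signal 2788.9), of ph-p (2757.7), a Polycomb group gene, and of Chro (2729.8), a chromosomal protein, followed. Ugalt, a UDP-galactose transporter gene, had a signal of 2640.4, and a site in intron sequence within both HmgD and HmgZ, which encode chromatin proteins, had 2450.5. Further sites lay within CG11050 (2271.8) and Trl (2264.8), the gene of the GAGA factor, and at the promoters of Art3 (2257.5), Tcs5 (2238.2) and CG1888 (2222.7). Lk6 (2013.8), Adf1 (2010.4) and CG32772 (1992.7) held sites in introns, and Shc (1888.2) and CG5611 (1882.7) at promoters. The others were at CG9663, CG9147, CenG1A, CG13921, Sox14, Tina-1 and CG8320, with signals from 1665.1 upward, and at 13035155 to 13035518 on 2R, an intergenic site with a signal of 1815.5 whose nearest coding TSS, that of CG13323, was 11922 bp away. In all, 16 of the 25 were named by a TSS, 8 by the gene they lay in and 1 by position. None ranked below 50 in replicate 1, 48 in replicate 2 or 71 in replicate 3.

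Comparison of passing sites with called regions that did not pass asked where in genes the passing sites lay. Promoters held 1828 of the 3922 passing summits, or 46.6% (95% exact binomial interval 45.0 to 48.2), against 19.6% of the 14842 regions that did not pass and 13.6% of the genome. All passing sites were among the 6047 pooled regions with a q under 0.05, so most regions that did not pass lacked such a q. The comparison is thus largely with background and not with sites that nearly passed. Coding exons were nearly free of passing sites, with 8 summits (0.204%) against 1264 (8.52%) of the regions that did not pass. Introns held 34.9% against 43.0%, and intergenic sequence held 16.3% against 25.3%. The log2 odds ratio was 1.84 for promoters (SE 0.0550, p = 1.18e-240, two-sided Fisher's exact test), -5.42 for coding exons (adjusted p = 1.13e-118; -3.89 within strata of summit GC, chosen after the data were examined), -0.49 for introns (adjusted p = 6.33e-20) and -0.79 for intergenic sequence (adjusted p = 3.04e-33). In 3' UTRs, which held 23 passing summits (0.586%) against 1.93%, it was -1.71 (exact test, adjusted p = 1.12e-10). The 5' UTRs (14 summits, adjusted p = 0.0509) and other exons (38 summits, adjusted p = 0.789) did not pass the exact test. Among each replicate's N best summits, promoters held 44.4% ± 3.21 (SD, n = 3), and coding exons held 0.680% ± 0.472, or 0.446% without replicate 3. In each of the 3 replicates promoters held a larger share of the N best than of the rest of the list, where they held 13.2, 20.5 and 18.9%.

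**Figure D3:**
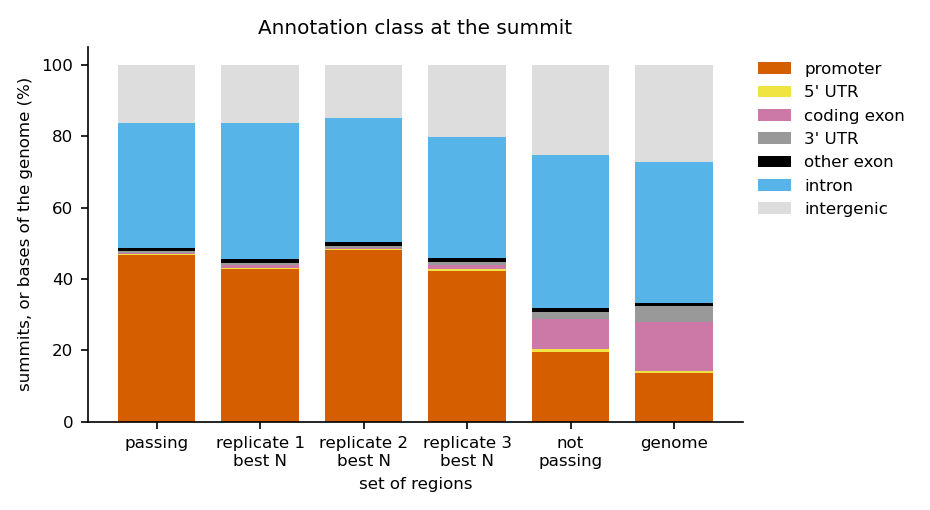
Share of summits, or of genome bases, in each annotation class (y axis, %) for passing sites, the N best-ranked summits of each replicate, regions that did not pass, and the genome (x axis). Promoters hold 46.6% of passing summits and 19.6% of those that did not pass, and coding exons hold 0.204 and 8.52%.

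Passing sites lay at similar density on the X and most large autosomal arms, were somewhat fewer on 2R and were sparse on chromosome 4. The density was 31.1 sites per Mb on 2L, 25.9 on 2R, 30.3 on 3L, 29.3 on 3R and 31.0 on the X. The X held 1.06 times the autosomal density (two-sided exact binomial p = 0.137), and the ratio over the replicates was 1.05 ± 0.0770 (SD, n = 3), so no difference was shown. Chromosome 4 held 14 sites, or 10.4 per Mb (95% Poisson interval 5.68 to 17.4), which was 0.356 times the density of the other autosomal arms (exact binomial p = 7.72e-06), a test added after the data were examined. Replicate 3 differed there, with 20.8 sites per Mb among its N best against 6.68 in replicate 1 and 8.16 in replicate 2. Replicate 3 also had 362 called regions on chromosome 4, 1.32% of its list, against 0.317% of the list of replicate 1 and 0.591% of that of replicate 2.

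Gene lists were compared to ask which kinds of genes had passing sites at their promoters. No control library was analysed here, so signal at promoters that did not depend on the tagged protein could not be told apart from binding. A passing summit lay within 500 bp of a TSS of 2220 of 13945 protein-coding genes (15.9%). Among the lists, promoters of cytoplasmic ribosomal protein genes had the highest share bound by passing sites, at 48 of 85 (56.5%, 95% exact binomial interval 45.3 to 67.2), with RpS27 (signal 791.8), RpL34b (764.6), RpL7 (755.7) and RpL23A (522.9) the strongest. Genes of architectural and insulator proteins, which organise chromatin, were bound at 10 of 23 (43.5%), including Chro, Cp190 (985.3), M1BP (468.2) and pzg (453.7). Cell cycle and mitosis genes were bound at 13 of 32 (40.6%), led by mei-41 (547.9), Dp (545.5), CycE (464.4) and sti (401.8). The list of RNA polymerase II and general transcription factors, called RNA polymerase II below, was bound at 20 of 64 (31.2%). It also holds subunits of the Mediator complex, among them its strongest members MED27 (707.5) and MED17 (623.4), followed by Polr2B (602.8) and Polr2H (553.1). Mitochondrial ribosomal protein genes were bound at 22 of 73 (30.1%), with mRpS10 (2257.5), mRpS23 (1732.7), mRpL41 (1544.9) and mRpL23 (1440.5) the strongest. The sites of mRpS10 and mRpS23 are those named above at Art3 and CenG1A.

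By two-sided Fisher's exact test against all other coding genes, the log2 odds ratio was 2.799 for cytoplasmic ribosomal proteins (SE 0.316, adjusted p = 3.39e-16), 2.04 for architectural proteins (SE 0.595, adjusted p = 0.00594), 1.88 for the cell cycle (SE 0.512, adjusted p = 0.00305), 1.29 for RNA polymerase II (SE 0.387, adjusted p = 0.00603) and 1.21 for mitochondrial ribosomal proteins (SE 0.366, adjusted p = 0.00603). Cytoplasmic ribosomal protein genes were bound at 32.9, 49.4 and 71.8% among the N best summits of replicates 1, 2 and 3, a mean of 51.4% ± 19.5 (SD, n = 3). Their first place was not steady across replicates. The cell cycle was below them in replicate 2, at 43.8%, but above them in replicate 1, at 40.6%. Without replicate 3 the mean was 41.2% for cytoplasmic ribosomal proteins and 42.2% for the cell cycle. With the sites shared by replicates 1 and 2 the log2 odds ratio of cytoplasmic ribosomal proteins was 1.51 (exact test, adjusted p = 0.000248). It was 1.88 for architectural proteins, 1.85 for the cell cycle and 1.74 for RNA polymerase II. Architectural proteins had 42.0% ± 5.02, the cell cycle 39.6% ± 4.77 and RNA polymerase II 32.3% ± 2.39. All these lists but mitochondrial ribosomal proteins, at 25.6% ± 3.95, passed in each of the 3 replicates, and that list passed in 1. By the exact test against genes with any pooled summit at the promoter, cytoplasmic ribosomal proteins still passed (48 of 70, log2 odds ratio 1.16, adjusted p = 0.0109), but mitochondrial ribosomal proteins (adjusted p = 0.283), the cell cycle (0.604), architectural proteins (0.574) and RNA polymerase II (0.423) did not. Their log2 odds ratios kept their direction, in the same order 1.01 (33 genes), 0.70 (21), 0.97 (15) and 0.87 (31), so fewer genes may account for part of the contrast. With the nearest gene only for each summit, mitochondrial ribosomal proteins (exact test, adjusted p = 0.9001) and RNA polymerase II (0.376) did not pass, and the former also did not with the 1961 strongest sites (0.164) or with the sites shared by replicates 1 and 2 (0.269).

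Promoters of genes for odorant and gustatory receptors (0 of 179) and cuticle proteins (0 of 111) carried no passing site, which allows a share of up to 2.04 and 3.27% (95% exact binomial). The log2 odds ratio was -6.11 for receptors (exact test, adjusted p = 6.03e-13) and -5.41 for cuticle proteins (adjusted p = 5.47e-08), and both were at 0 in each replicate. Among genes with a pooled summit both still passed, at 0 of 14 each (exact test, adjusted p = 0.00113). Replication-dependent histone genes were also at 0 of 111, but none had even a background region of the pooled list at its promoter. These genes are near-identical tandem copies, so whether a region could be called there is open, and their test, which treats them as independent, is not read as a depletion. Among all genes, tRNA genes were bound at 6 of 290 (2.07%, log2 odds ratio -2.78, exact test, adjusted p = 1.27e-10) and small nuclear and nucleolar RNA genes at 13 of 301 (4.32%, -1.74, adjusted p = 1.05e-06). Both passed in each of the 3 replicates, but the latter did not against genes with a pooled summit (exact test, adjusted p = 0.574) or within 1000 bp (0.360). The strongest site at a tRNA gene was at tRNA:Tyr-GTA-1-8 (845.8), and at a nucleolar RNA gene at snoRNA:Or-aca5 (358.9).

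The other 20 of the 30 lists did not pass. Polycomb and trithorax group genes were bound at 9 of 29 (exact test, adjusted p = 0.0993), with ph-p, brm (910.5), E(z) (775.4) and Su(z)12 (332.3) the strongest, and passed with the nearest gene only for each summit (0.0439). Maternal germ plasm and piRNA genes had 8 of 28 (0.168), among them papi (740.0), egl (494.0), orb (352.6) and piwi (319.9), and passed with the 1961 strongest sites (0.0472). Testis-specific genes had 0 of 23 (0.0993) and passed within 1000 bp (0.0430). Translation factors had 13 of 54 bound, including eIF4EHP (1531.9) and eIF6 (1500.3), the respiratory chain 15 of 84, including ND-MWFE (697.1), DNA replication 6 of 29, including Mcm2 and RPA1 at a shared site (535.0), heat shock proteins 5 of 21, including Hsp27 (931.3), and the proteasome 4 of 32, including Rpn5 (451.5). Among developmental genes, the Notch-responsive E(spl) genes had 3 of 11, E(spl)m3-HLH (1177.8), E(spl)m7-HLH (703.9) and E(spl)mdelta-HLH (618.2). Mesoderm and muscle genes had 6 of 28, including Poxm (596.7) and mbc (495.0), cellularization genes 3 of 18, including tst (549.0), and dorsoventral genes 3 of 28, including stumps (659.8). Neural genes had 2 of 25, elav (1075.2) and mira (186.5). Gap and terminal genes had 2 of 16, fkh (189.1) and cnc (189.0), and endoderm genes had 1 of 8, again fkh. Pair-rule and segment-polarity genes had 1 of 20, nkd (226.0), Hox genes 1 of 8, Antp (130.6), and hemocyte genes 1 of 18, PPO3 (150.4). Yolk and fat body genes (0 of 9) and chorion genes (0 of 8) had none.

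**Figure D4:**
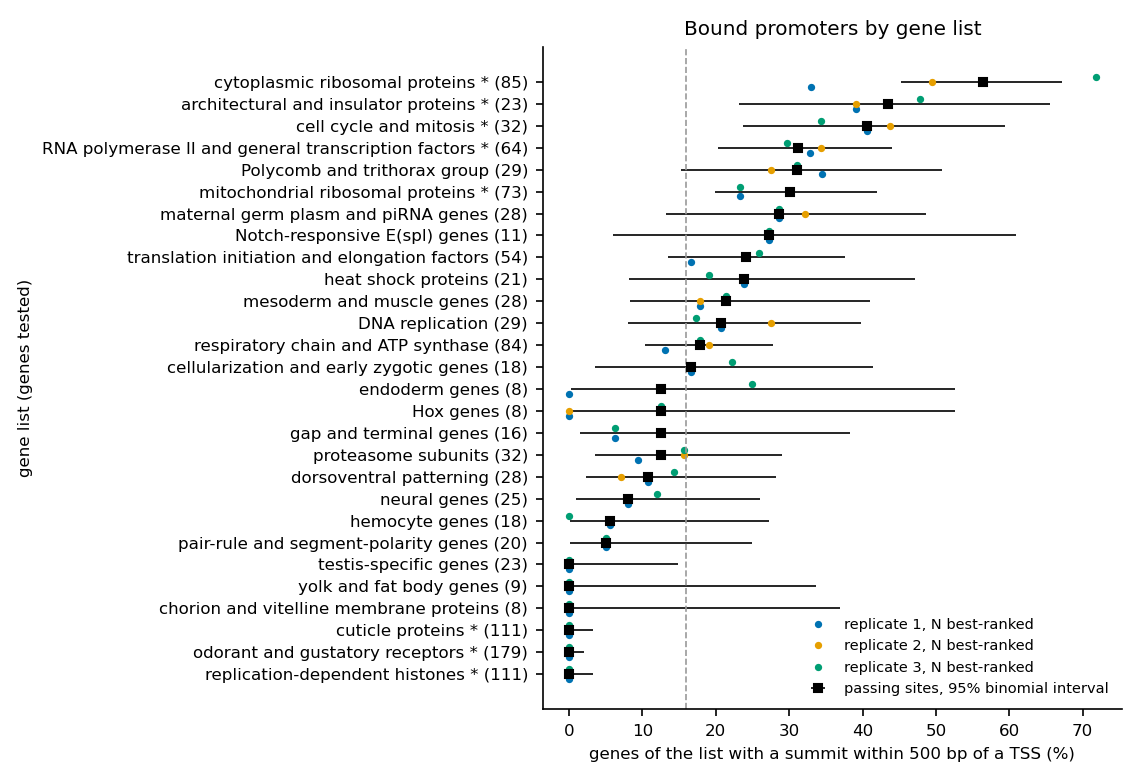
Share of the genes of each list with a summit within 500 bp of a TSS (x axis, %) by gene list (y axis, number of genes tested), for passing sites with the 95% binomial interval (squares) and for the N best-ranked summits of each replicate (points). The dashed line is the share of all coding genes, 15.9%, and an asterisk marks lists with an adjusted p under 0.05; histone genes had no called region in the pooled list, and the 2 classes of RNA genes are not drawn.

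Sequence at the summits was compared with the flanks of the same sites to ask which motifs marked them. The DRE, the site of the promoter factor DREF, was in 0.943% of summit windows against 0.204% of flanks, and the CTCF core was in 1.45 against 0.357%. GATA sites were in 24.0 against 15.8%, and the homeodomain core TAATTA was in 10.99 against 5.74%. The GAGA repeat, bound by the GAGA factor, was in 0.561 against 3.37%, and the Myc E-box was in 0.688 against 1.81%. Of 26 motifs, 7 were higher at summits, 4 were lower and 15 did not pass, and the 11 that passed did so in each of the 3 replicates. By the exact McNemar test, the log2 ratio of discordant pairs was 2.14 for the DRE (adjusted p = 4.44e-05), 2.07 for CTCF (adjusted p = 6.25e-07), 1.37 for the TATA box (adjusted p = 4.1e-07), 1.15 for Motif 7 (adjusted p = 0.000680), 0.98 for TAATTA (adjusted p = 1.18e-15), 0.77 for GATA (adjusted p = 5.36e-19) and 0.24 for the BEAF-32 core (adjusted p = 0.0351). It was -2.61 for GAGA (exact test, adjusted p = 3.28e-19), -1.88 for the DPE (adjusted p = 5.18e-10), -1.45 for the Myc E-box (adjusted p = 2.06e-05) and -1.07 for the Snail E-box (adjusted p = 2.09e-07).

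The motifs read backwards, which keeps their base composition, moved in the same way for some and not for others. The reversed GATA site was in 24.7 against 13.4% of windows, the TATA box in 4.95 against 2.01% and TAATTA in 11.6 against 4.97%, and the log2 ratio was 0.51 for the reversed BEAF-32 core, -1.32 for the DPE and -1.36 for the Snail E-box. It was 0 for reversed CTCF (0.0765% in both), -0.45 for Motif 7 (0.331 against 0.459%), 0.74 for the DRE (0.306 against 0.178%) and 0.37 for the Myc E-box. The first 3 of these were rare when reversed, and their difference from the motif did not pass (exact test, adjusted p = 0.366, 0.0618 and 0.366). The GAGA repeat reads the same backwards, so its lower share at summits had no such control for base composition. Against the reversed form, a comparison added after the data were examined, 2 of the 25 motifs that have one passed by Fisher's exact test. These were the Myc E-box (exact test, adjusted p = 4.21e-05) and the Twist E-box (adjusted p = 0.0209), which did not pass against the flanks and was raised at summits less than its reversed form (log2 ratio 0.18 against 1.20). Within promoters, against promoter regions that did not pass, the log2 odds ratio was -0.03 for the DRE, -0.08 for CTCF, -0.03 for Motif 7 and -0.10 for the BEAF-32 core, none of which passed. There the TATA box (exact test, adjusted p = 0.422) and the Myc E-box (1.00) did not pass either. Motif 7 also did not pass against all regions that did not pass (exact test, adjusted p = 0.211), with the 1961 strongest sites (0.308) or with the sites shared by replicates 1 and 2 (0.531), and the BEAF-32 core did not with the 1961 strongest (0.0992). Motif 1, the M1BP core and Motif 6 were higher at summits within 100 bp (exact test, adjusted p = 0.000704, 0.00613 and 0.00691).

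The 7-mers showed the same A/T-rich sequence. Of 8192, 3751 passed, 1232 higher at summits and 2519 lower, with a median of 2 and 5 G or C bases, and all 64 without G or C were higher. TTAAAAA was in 666 summit windows against 178 flanks (17.0 against 4.54%, exact test, adjusted p = 2.88e-68), followed by TTTAAAA (631 against 166), ATTTTAA (592 against 164), ATTTAAA (543 against 158) and TATTTAA (538 against 158). CACACAC was in 43 against 237, ACACACA in 72 against 256, CAACAAC in 50 against 210, CAGCAGC in 34 against 179 and CTGCTGC in 33 against 166. GC content, a measure chosen after the data were examined, was 32.2% at passing summits and 44.4% in their flanks, lower at 86.1% of sites. Over the replicates' N best it was 33.1% ± 0.659 (SD, n = 3) at summits. Regions that did not pass had 40.6 and 42.1%.

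**Figure D5:**
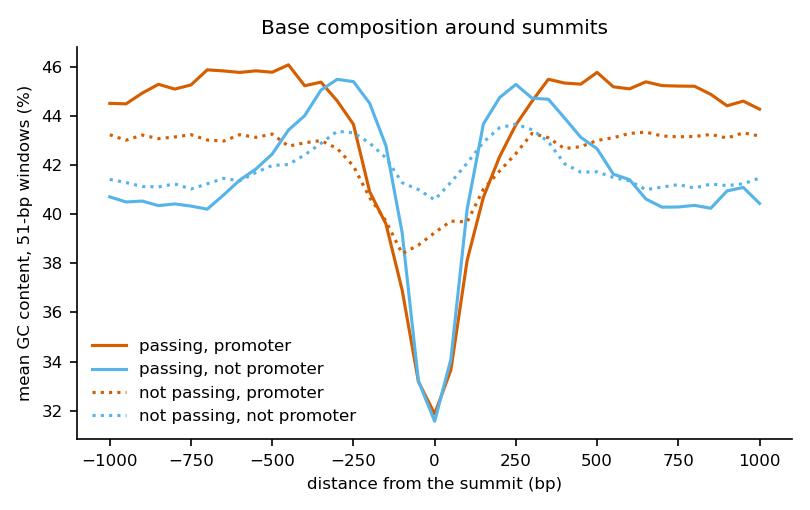
Mean GC content in windows of 51 bp (y axis, %) by distance from the summit (x axis, bp) for passing sites and regions that did not pass, in promoters and outside them. Passing sites in both places dip at the summit, and regions that did not pass dip less.

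The lists on the dm3 build gave similar values. The authors kept 3815 sites there, 22.02% of their pooled list against 20.9% on dm6. The pairs of replicates shared 78.3, 61.0 and 67.4% of their best-ranked summits, and rho was 0.836, 0.513 and 0.536. Replicate 1 held 30000 regions on that build as well, replicate 2 held 19974 and replicate 3 held 24920.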

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

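Location within strata of summit GC, the sites shared by replicates 1 and 2, motifs against their reversed forms and random draws were alternatives chosen after the data were examined; the others were fixed before. Without leave-one-out values, 46 summary values stayed within the spread, their side of the threshold or 1.5 times the count, and 9 did not. A mean of 3 replicates without 1 of them moves by less than their SD by construction, so it says nothing on stability; without replicate 3 the mean share bound was 0% for Hox genes, 6.25% for endoderm and 5.56% for hemocyte genes, against 4.17, 12.5 and 3.70%. Within strata of GC the log2 odds ratio was 1.71 for promoters and -3.89 for coding exons. Of the values for single gene lists 144 kept direction and side of the threshold, 10 no longer passed, 3 newly passed and 21 turned direction, and of those for motifs 101 (1 of them at exactly 0), 6, 7 and 16. Summits in common fell to 50.6% at 50 bp and 53.1% for the best-ranked 7844, and ranged from 60.7 to 78.4% without 1 replicate, where rho ranged from 0.518 to 0.833. Passing sites found averaged 79.9% at 50 bp, and in the N best 70.1% at 50 bp and 95.5% for the 1961 strongest. With genes with a pooled summit as background 4 lists passed, 5 motifs passed among promoters and 2 against the reversed form, and 498 6-mers were higher at summits, of the fewer that exist.

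Lists that turned direction passed in neither setting. Their log2 odds ratios against genes with a pooled summit were -0.45 for the respiratory chain, -0.18 for DNA replication, 2.35 for gap genes, 0.0302 for pair-rule genes and -0.71 for both Hox and endoderm genes. Within 250 bp they were 0.20 for the proteasome, -1.22 for Hox, -1.66 for E(spl), -0.0017 for mesoderm and -0.68 for cellularization genes. Within 1000 bp they were -0.013 for the respiratory chain and 0.057 for dorsoventral genes. With the nearest gene only they were -0.028 for the respiratory chain, 0.43 for gap and 0.097 for dorsoventral genes, with the 1961 strongest sites -0.16 for the respiratory chain and -0.88 for both Hox and endoderm genes, and with sites of replicates 1 and 2 -1.35 for both.

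Motifs that turned direction within 100 bp were Motif 5 (0.57) and Stat92E (-0.044), and against regions that did not pass CREB (0.19) and AP-1 (0.38). Among promoters they were Motif 1 (-1.23), the M1BP core (-0.36), the DRE (-0.033), BEAF-32 (-0.096), Motif 7 (-0.033), CTCF (-0.082), Stat92E (-0.36), CREB (1.57) and AP-1 (0.59), with the 1961 strongest sites the M1BP core (-0.63), where Motif 1 was at 0, and with sites of replicates 1 and 2 the M1BP core (-0.16) and Pho (0.15). The cause was not tested. The N best summits of the pooled list are the passing sites themselves, so that alternative gave no value. Histone and yolk genes had no pooled summit and gave none. Depth is unknown and limits the weaker regions in a way that was not measured.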

Other observations

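Of the tests in this part, that of the order of sites within promoters was set down before its result was seen, and the others were chosen after. Passing sites near coding genes lay mostly just upstream of the TSS. Of 1714 summits within 500 bp of the nearest coding TSS, 1498 (87.4%) were upstream, at a median of -139 bp, against 70.1% of 2549 regions that did not pass (log2 odds ratio 1.56, p = 8.28e-42, Fisher's exact test). The N best of the replicates had 86.4% ± 1.45 (SD, n = 3). A pair of divergent TSSs within 1000 bp of each other flanked 714 of the summits (41.7%) against 530 (20.8%) of those that did not pass (log2 odds ratio 1.44, exact test, p = 3.33e-48). A summit between such a pair lies upstream of both TSSs, so the upstream and divergent comparisons overlap and are not separate evidence. Both set passing sites against regions that were largely background.

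Some genes held many passing sites, more than the density of their chromosome arm gave for their length. Both shn, a regulator in BMP signalling, and ush held 12, where 1.51 and 2.00 were expected by density. Raf, a kinase of the MAPK pathway, held 11 (expected 1.501), and pnt, an ETS factor downstream of that pathway, held 10 (expected 1.64). CG1677 held 18 (expected 3.87), and the smaller genes CHES-1-like and CG14434 held 9 (expected 0.839) and 6 (expected 0.474). The highest count, 19 in kirre, goes with its length of 394.1 kb, for which 12.2 were expected. At least 5 sites lay in 63 of the 1351 genes with any site, nested genes count the same site, and the excess over density was not tested.

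Replicate 3 had a cluster of called regions around CG16815. More regions in that replicate everywhere is argued against, since 0.0502% of 13945 windows centred on coding genes showed as large an excess. Of those 7 windows, 5 were CG16815 and its neighbours Prosalpha6T, Jhbp13, Mabi and Jhbp14. The others lay on 3R, at CG43131 (27 regions in replicate 3 against 8 and 9 in replicates 1 and 2) and E(spl)m3-HLH (28 against 10 and 11). As large an excess thus also occurred away from the tagged gene. Replicates 1 and 2 together held 7 regions where their density gave 15.8, so they showed no excess of calls there. These counts are part of the pattern itself, and the further file behind each list is not described. They therefore cannot show or exclude extra copies of the segment in all 3 libraries alike. Extra copies of the segment in the library of replicate 3 remain a candidate explanation, as GC at the cluster's summits lay 5.05 percentage points above that of regions of the same rank in that replicate (one-sided permutation p = 0.0135), though not detectably above the mean of all its regions outside the N best (two-sided permutation p = 0.224). Neighbouring regions share their local base composition, so these tests do not single out extra copies, and no biological explanation was tested, as the design has 1 group.

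Passing summits sat at the centre of A/T-rich stretches. Promoter sequence as the whole source is argued against, since passing summits outside promoters had a GC deficit of 11.2 percentage points against their flanks. Regions that did not pass had a deficit of 1.56 points, so called regions in general, background included, did not share a deficit of that size. Of the 18764 pooled regions, 6047 had a q under 0.05, all passing sites among them. Most regions that did not pass were thus weak, and whether every enriched region has such a deficit was not tested. Genomic stretches with at most 30.7% GC and flanks of at least 44.6% were then taken, where both cutoffs are medians of the passing sites themselves. Of passing sites, 57.5% lay within 150 bp of such a stretch, a share that the cutoffs partly built in and for which no chance level was computed. A passing summit was held by 7.83% of 13922 stretches in promoters and 1.51% of 74130 elsewhere. The log2 odds ratio within strata of stretch and flank GC was 2.42 (95% interval 2.30 to 2.55), so stretches of like GC did not hold a passing summit equally often. The promoter share of the same sites was already known to be raised, also within strata of summit GC. This value therefore largely restates that result and is not separate evidence on what set the sites. A preference of the tagged protein or of open chromatin for such stretches may remain, and no biological explanation was tested.

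Replicate 3 ranked the sites differently from replicates 1 and 2. Noise among weak sites is argued against, since among the 250 best-ranked summits the pairs with replicate 3 shared 59.6% and replicates 1 and 2 shared 85.0%. A shift of promoter sites in general as the whole source is argued against, since the rho of replicates 1 and 2 exceeded the mean rho of the pairs with replicate 3 by 0.206 within the 1828 promoter sites (95% bootstrap interval 0.181 to 0.235) and by 0.390 within the 2094 others (0.353 to 0.429), against 0.306 over all sites. These intervals cover the sampling of sites, which are not independent, and not the spread between replicates, as replicate 3 is 1 library. A difference in the embryos, the precipitation or the library of replicate 3 may each remain, and no biological explanation was tested.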
